A study of Mus musculus with 4 samples.

How the data were processed

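Total RNA from 4 mouse brain regions at embryonic day 17.5 was measured on 4 Affymetrix arrays, 1 per region. Per the labels' protocols, RNA was isolated with Trizol and RNeasy columns, converted to sense-strand cDNA with the Ambion WT Expression Kit and biotin-labelled with the Affymetrix WT Terminal Labeling Kit. Each array was hybridised with tissue pooled from 13 to 16 mice, so variation between animals is averaged within an array and cannot be estimated. Per the submitters' processing notes, Affymetrix Expression Console was used. Its version, the summarisation algorithm, the background correction, the normalization and the genome build are not given in the sources used here.

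The authors' deposited table held 1 log2 value per probe set and array, to 2 decimals. That the scale is log2 was inferred from the values, which lay between 2.43 and 14.57, a range far too small for linear scanner signals. Medians of the 4 columns were close to each other (8.07 to 8.13), and the values were taken as already scaled between arrays by the authors. Such scaling can remove a difference in total RNA per cell or in the general level between regions. Array signals of weak genes approach a background level, so a fold difference between a bright and a dim region can be compressed, and a low value is not a measure of absence. No coordinates are given because no build is named for the table.

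Probe sets were named through the annotation table of the array, which dates from 2016. Of 35556 probe sets, 21789 had 1 gene symbol and 1621 had several, and 12146 were without an entry and are unnamed here. Of those with 1 symbol, 21698 were matched by Entrez ID to the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Probe sets with several symbols were not used for genes. For the 999 genes with several probe sets, the probe set with the highest mean level over the arrays gave the gene's level, leaving 19938 genes. Some list genes have no singly named probe set and are unnamed here. All value columns of the table were assigned to samples, by the sample identifiers that name them.

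With 1 array per region no test was made. The size rules, the level floor, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. A gene was compared when its highest level over the 4 arrays exceeded 8.56, the 50th percentile of all gene levels, which 10908 genes did. Higher meant at least 1 log2 unit above the highest of the other 3 arrays, lower at least 1 log2 unit below the lowest, and for each of the 6 pairs of regions a difference of at least 1 log2 unit in either direction. For each region the 10 genes with the widest gap above and the 5 with the widest gap below the other arrays were named, leaving out predicted genes, small RNAs, olfactory and vomeronasal receptors, pseudogenes and antigen receptor segments, and for each pair the 3 with the largest difference in each direction. From each list up to 4 members past the rule were named by gap, or, where none passed, up to 2 with the largest difference from the mean of the others. Other list members are named with their levels where their list is described, and those given as examples were picked after their values were seen.

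There were 39 gene lists, covering regional neuron classes, other cell types the tissue could hold, processes, and sample quality. For each list and region the median of the members' differences from the mean of the other 3 arrays was taken over members above the floor, and set beside the medians of 10000 random lists of the same size, drawn in 20 bins of mean level. The list of ribosomal protein genes was narrowed by a pattern to symbols of the large and small subunit proteins. The size rule was tested on simulated data for 10908 genes with noise of SD 0.145, taken from the background genes. It called 96% to 98% of genes raised by 1.5 log2 units in each simulated region, 100% of those raised by 2 or 3, and 0% of those raised by 0.5 or left unchanged. That noise covers background probe sets on these arrays, not differences between animals or dissections. It comes from genes that all lay below the floor, while the simulated genes were those that exceeded it. The simulation therefore gives no error rate for the compared genes.

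Alternatives were no level floor, a floor at the 75th percentile, a floor at the 95th percentile of the background genes' levels, quantile normalization of the 4 columns, the mean of a gene's probe sets, a rule of 2 log2 units, and the mean of the other arrays, or for list medians their highest, as comparator. The lowest of the other arrays, for lists that lay low, was added after seeing the data. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used.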

Results

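Gene expression was measured in 4 regions of the mouse brain at embryonic day 17.5: the cerebellum, the olfactory bulb, the pontine nucleus and the superior colliculus. The pontine nucleus is a hindbrain nucleus that projects to the cerebellum, and the superior colliculus is the visual part of the midbrain roof, or tectum. The embryos were of the outbred ICR stock. Tissue of several mice was combined for each region and hybridised to 1 Affymetrix array, with 13 mice for the cerebellum, 14 for the olfactory bulb, 15 for the pontine nucleus and 16 for the superior colliculus. Those pool sizes increase by exactly 1 in the order in which the samples are listed, and they are given as the labels state them. There were no replicates, so no difference reported here has an SD or a p-value, and a difference between regions cannot be separated from a difference between single pooled preparations. The number of arrays limits the precision of every value.

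The values were log2 signals. Over 35556 probe sets the array medians were 8.13 for the cerebellum, 8.10 for the olfactory bulb, 8.11 for the pontine nucleus and 8.07 for the superior colliculus, and the signals ranged from 2.43 to 14.57. Of 19938 named genes, 10908 had a level above 8.56, the median of all gene levels, on at least 1 array and were compared. A gene was called higher in a region when its level lay at least 1 log2 unit (2-fold) above the highest of the other 3 arrays, and lower when it lay at least 1 log2 unit below the lowest of them. For scale, 207 vomeronasal receptor and beta defensin genes, taken as a background set, had a median level of 5.19 and a 95th percentile of 7.32. Gaps are printed as measured throughout. Where the lower level in a comparison lies below that percentile, the printed gap is to be read as a lower bound, which holds for 11 of the 40 genes named as higher in a region and for many of the pair differences. In that set 95% of the differences from the mean of the other arrays lay between -0.32 and 0.35, and no gene passed the size rule before the level floor was applied. No gene of the set lay above the floor, so the set gives no rate of false calls among the compared genes.

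The comparison asks which genes set each region apart from the other 3. The size rule called 66 genes higher and 17 lower in the cerebellum, 106 higher and 47 lower in the olfactory bulb, 87 higher and 107 lower in the pontine nucleus, and 78 higher and 18 lower in the superior colliculus. With a difference of 2 log2 units (4-fold) these counts were 12 and 0, 37 and 5, 21 and 13, and 15 and 1. Measured against the mean of the other 3 arrays instead of their highest or lowest, they were 264 and 100, 255 and 168, 180 and 395, and 241 and 179.

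**Figure D1:**
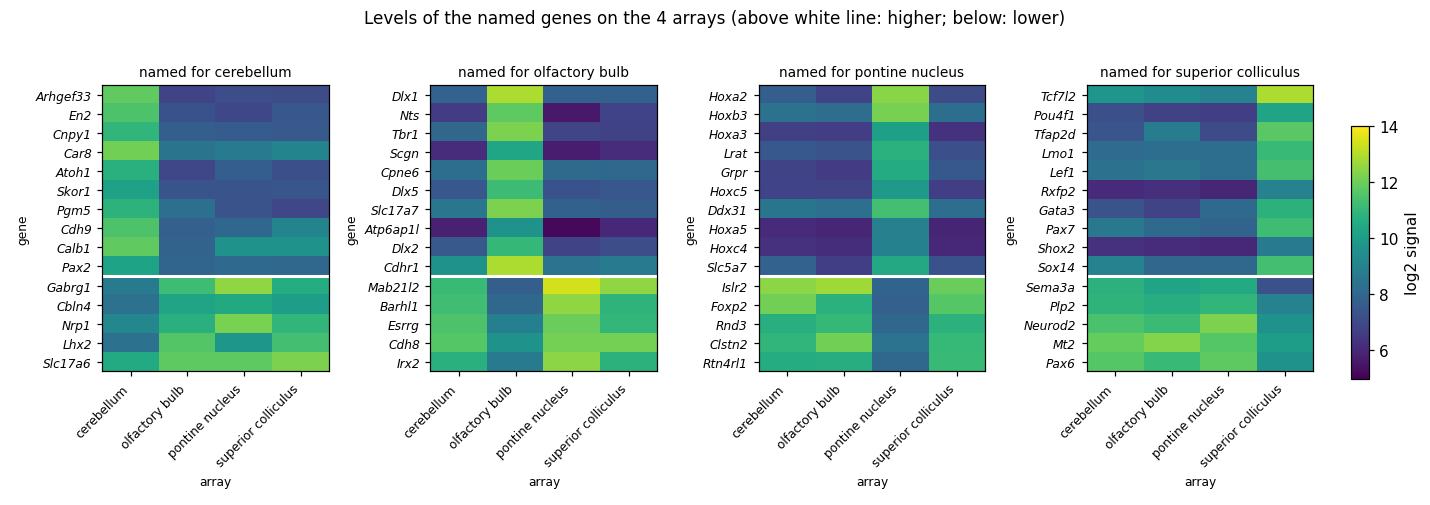
Levels of the genes named for each region, as log2 signal (colour scale) on the 4 arrays (horizontal axis), with 1 panel per region and 1 line of cells per gene. Genes above the white line are the 10 genes with the widest gap above the other arrays, such as Dlx1 at 12.89 in the olfactory bulb, and genes below it are the 5 with the widest gap below them, such as Islr2 at 7.90 in the pontine nucleus.

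In the cerebellum the 10 named higher genes included markers of granule cells, Purkinje cells and inhibitory interneurons. Arhgef33 (probe set 10447108) read 11.79 against at most 7.11 elsewhere, a level within the range of the background genes. En2, a homeobox gene of the midbrain-hindbrain boundary, was higher by 4.03 log2 units and Cnpy1 by 3.19. Atoh1, the transcription factor of granule cell precursors, read 10.70 against at most 7.70. Car8 and Calb1, genes of Purkinje cells, were higher by 3.02 and 2.17, and Pax2, a gene of cerebellar inhibitory interneuron precursors, by 2.17. The remaining genes of this group were Skor1, Pgm5 and Cdh9, higher by 2.76, 2.52 and 2.43. The lower genes had smaller gaps. The GABA-A receptor subunit gene Gabrg1 was 3.71-fold lower than in the next lowest region, the cerebellin family gene Cbln4 3.25-fold, the semaphorin co-receptor gene Nrp1 2.95-fold, the LIM homeobox gene Lhx2 2.60-fold and the vesicular glutamate transporter gene Slc17a6 2.38-fold.

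Among the lists of marker genes, the Purkinje cell list had 13 members above the level floor, all of them above the mean of the other arrays in the cerebellum, with a median difference of 1.77. Of these, 6 passed the size rule there, among them Car8, Calb1, Skor2 at 9.13 against at most 7.16, and Pcp2 at 9.27 against at most 7.69. Against the highest of the other arrays the Purkinje median was 0.82. The granule lineage list, with 20 members above the floor, had a median difference of 0.82 in the cerebellum and 0.93 in the pontine nucleus, against -0.53 in the olfactory bulb and -0.95 in the superior colliculus. In the cerebellum 3 of the 20 passed the size rule, namely Atoh1, Mfap4 at 11.75 against at most 9.75, and Pde1c by 1.40. Measured against the highest of the other arrays, the cerebellar median of that list was -0.17. Several granule lineage genes lay close together in the cerebellum and the pontine nucleus, such as Zic1 at 12.90 and 13.36, Pax6 at 11.64 and 11.76, and Unc5c at 12.21 and 12.36. Neurod1 differed between them, at 12.30 in the cerebellum and 6.85 in the pontine nucleus. The list of cerebellar GABAergic progenitor genes had only 3 members above the floor. Of these Pax2 and Kirrel2, the latter by 1.16, passed the rule, and the median was 1.36, or 0.63 with no level floor.

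In the olfactory bulb the higher genes included those of forebrain inhibitory interneurons and of the bulb's projection neurons, the mitral and tufted cells. The homeobox gene Dlx1 (probe set 10472809) read 12.89 against at most 7.84 elsewhere, 33.1-fold higher, and its relatives Dlx5 and Dlx2 were higher by 3.72 and 3.51 log2 units. The neuropeptide gene Nts (neurotensin) read 11.78 against at most 6.82. Tbr1, a T-box transcription factor of projection neurons, was higher by 4.24, the vesicular glutamate transporter gene Slc17a7 by 3.71 and Cdhr1, a cadherin-related gene of mitral cells, by 3.27. The calcium-binding protein genes Scgn and Cpne6 were higher by 4.12 and 3.74, and Atp6ap1l by 3.58. Lower genes were Mab21l2 (probe set 10499132), at 7.73 against at least 11.06 and 10.1-fold lower, and the homeobox genes Barhl1, 6.92-fold lower, and Irx2, 4.06-fold lower. Esrrg, a nuclear receptor gene, and Cdh8, a cadherin, were 4.29-fold and 4.14-fold lower.

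All 18 members of the olfactory bulb interneuron list that lay above the floor read above the mean of the other arrays in the bulb. Their median difference was 1.59, and 8 passed the size rule, led by Dlx1, Dlx5, Dlx2 and Sp8, the last by 3.23. Th, the enzyme gene of dopamine synthesis, was higher by 1.85. The mitral and tufted cell list had a median of 2.08 over 11 members, of which 5 passed: Tbr1, Slc17a7, Cdhr1, Tbx21 by 2.21 and Eomes at 12.21 against at most 10.51. The telencephalon list had a median of 1.79 over 8 members, of which Fezf2 passed by 2.02 and Neurod6 by 1.33. Emx2 and Lhx2 did not pass because both were also high in the superior colliculus, at 10.13 against 9.81 and at 11.59 against 11.31. Against the highest of the other arrays the medians of the interneuron, mitral and telencephalon lists were 0.85, 0.84 and 0.71. Some genes listed for non-neuronal and peripheral cells were also higher in the bulb. Of 6 genes of olfactory ensheathing and Schwann glia above the floor, 3 passed the rule in the bulb, Frzb by 2.67, Npy by 2.18 and Erbb3 by 1.19, with a list median of 0.93. Of the 6, 4 lay above and 2 below the mean of the other arrays. Npy is also counted among the neuropeptide genes, and 4 of the 9 measured members of this list belong to another list. All 7 meningeal and fibroblast genes above the floor lay above the mean of the other arrays, with a median of 0.53 and Dcn higher by 1.94. Olfactory sensory neuron genes did not, with a median of -0.41 over 3 genes, or -0.0567 over all 11 measured genes, and Omp, their classical marker, lay below the floor at 7.92.

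Of the 10 genes named as higher in the pontine nucleus, 6 were Hox genes, which pattern the hindbrain and spinal cord. Hoxa2 (probe set 10544751) read 12.41 against at most 7.71 elsewhere, 26.0-fold higher. Hoxb3, Hoxa3, Hoxc5 and Hoxc4 were higher by 3.74, 3.43, 3.05 and 2.66 log2 units, and Hoxa5 read 8.92 against at most 6.12. The other named genes were Lrat, an enzyme gene of retinoid storage, higher by 3.27, the gastrin-releasing peptide receptor gene Grpr by 3.07, the choline transporter gene Slc5a7 by 2.59, and the RNA helicase gene Ddx31, which read 11.31 against at most 8.51. This array had the most lower genes of the 4. Islr2 (probe set 10594048) read 7.90 against at least 11.93 and was 16.3-fold lower, and the forkhead gene Foxp2 was 7.84-fold lower. Rnd3, the calsyntenin gene Clstn2 and Rtn4rl1, a Nogo receptor relative, were 6.06-fold, 5.74-fold and 5.70-fold lower.

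Of 21 measured Hox list members, 11 passed the size rule in the pontine nucleus, with or without the level floor. All 11 lay below the floor on the other 3 arrays, so the floor kept them only through their pontine level. Their median difference was 2.78, and that of all 21 was 1.66. With the floor at the 75th percentile the median was 3.71. Hoxc5, Hoxa5, Hoxc4, Hoxa4, Hoxd3, Hoxb4 and Hoxb5 did not pass that floor. The value of 3.71 therefore rests only on the brightest members, Hoxa2, Hoxb3, Hoxa3 and Hoxb2. The other 10 measured Hox genes lay below the floor on every array, such as Hoxb1 at 8.19 and Hoxc8 at 6.52 in the pontine nucleus. The list of pontine mossy fibre neuron genes did not stand apart as a whole. Over 14 members its median was 0.18 in the pontine nucleus, 0.025 with the floor at the 75th percentile and -0.47 against the highest of the other arrays. Of these 14, 3 passed the rule: Barhl1 by 1.25, the guidance receptor gene Robo3 by 1.23 and the cadherin gene Cdh7 at 11.56 against at most 10.56. GABAergic neuron genes were low, with a median of -1.70 over 6 genes, or -0.75 against the lowest of the other arrays, and the glutamate decarboxylase genes Gad1 and Gad2 read 8.92 and 9.20 against at least 11.03 and 10.47 elsewhere. The vesicular inhibitory transporter gene Slc32a1 also passed as lower, at 8.03 against at least 9.27. The glycinergic neuron list, which also holds Slc32a1, was not low as a whole, with a median of -0.03 over 6 genes. Of these, 3 lay above and 3 below the mean of the other arrays. Among them Glra1, which encodes a glycine receptor subunit, read 8.79 in the pontine nucleus against at most 8.12 elsewhere. Of the brainstem monoaminergic and motor list, 5 members lay above the floor, with a median of 1.41, or 0.18 with no level floor. Slc5a7, Slc18a3 and the serotonin transporter gene Slc6a4 passed as higher, the last 2 by 1.65 and 1.40. Apart from the named genes, 259 of 12146 probe sets without an entry in the annotation table lay at least 1 log2 unit above the other arrays in the pontine nucleus, against 7 in the cerebellum, 17 in the olfactory bulb and 8 in the superior colliculus. Unlike the gene counts, these were taken with no level floor.

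Several of the genes named as higher in the superior colliculus encode transcription factors. Tcf7l2 (probe set 10464084) and Lef1, nuclear effectors of Wnt signalling, read 12.88 and 11.34 against at most 9.70 and 8.56 elsewhere, higher by 3.18 and 2.78 log2 units. The POU homeobox gene Pou4f1 was higher by 3.08, Tfap2d by 2.86, Lmo1 by 2.82, Gata3 by 2.74 and Pax7, a gene of the dorsal midbrain, by 2.62. Rxfp2, a relaxin family receptor gene, Shox2 and Sox14 were higher by 2.78, 2.39 and 2.33. Among the lower genes the gap of Sema3a (probe set 10519717), which encodes a repulsive axon guidance ligand, was the widest. It read 7.24 against at least 10.24 elsewhere. Plp2 was 3.07-fold lower, Neurod2 2.97-fold, the metallothionein gene Mt2 2.93-fold and Pax6 2.77-fold. Plp2 was the only gene named for a region with several probe sets, and its 2 other probe sets also passed the rule.

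The midbrain tectum list had a median difference of 2.09 in the superior colliculus over 16 members, of which 9 passed the rule, led by Pou4f1, Tfap2d, Gata3 and Pax7. With no level floor its median was 1.13, and against the highest of the other arrays it was 1.39. En1 and En2, which belong to the same list, were higher in the cerebellum instead, by 1.34 and 4.03. Thalamic and pretectal genes were high as well, with a median of 1.45 over 7 members and Tcf7l2, Lef1 and Lhx9 past the rule, the last by 2.32. Without a level floor that median was 0.69, and against the highest of the other arrays it was 0.94. Of the same 7 genes, Slc6a4 and Prox1 were higher in the pontine nucleus instead, by 1.40 and 1.20. Midbrain dopamine neuron genes had a median of 0.59 over 4 members, which turned to -0.03 with no level floor, and none of them passed in this region.

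**Figure D2:**
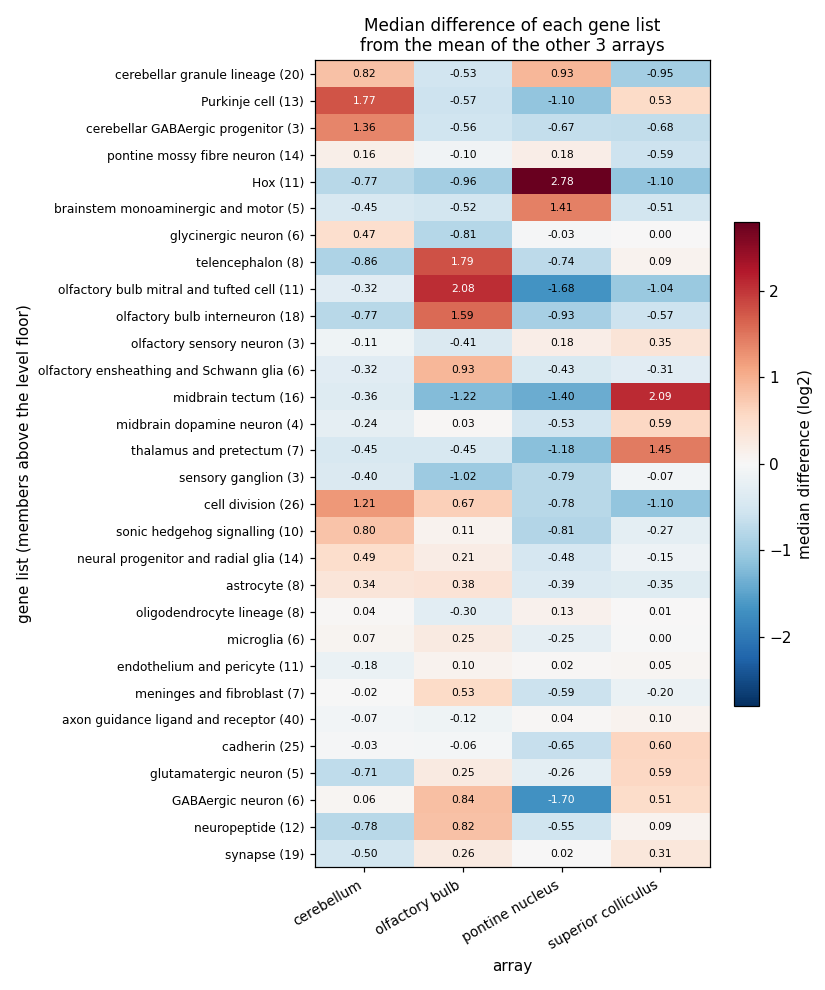
Median log2 difference of each gene list (vertical axis, with the number of members above the level floor in brackets) from the mean of the other 3 arrays, for each array (horizontal axis), for lists with at least 3 such members; red is higher and blue is lower. The highest values are those of the Hox list in the pontine nucleus (2.78), the midbrain tectum list in the superior colliculus (2.09) and the mitral and tufted cell list in the olfactory bulb (2.08).

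Genes of cell division were ordered across the regions. All 26 above the floor were highest in the cerebellum and second in the olfactory bulb, and 25 of them were lowest in the superior colliculus. The median differences from the mean of the other arrays were 1.21 in the cerebellum, 0.67 in the olfactory bulb, -0.78 in the pontine nucleus and -1.10 in the superior colliculus. The proliferation marker Mki67, for example, read 11.50, 10.93, 9.50 and 9.27 in that order, and the topoisomerase gene Top2a 10.83, 10.31, 8.76 and 8.50. No member passed the size rule in any region, since the medians of the paired differences were only 0.46 log2 units between the cerebellum and the bulb and 0.28 between the pontine nucleus and the superior colliculus. The cerebellum and the superior colliculus lay 1.71 apart, and all 26 genes differed by at least 1 log2 unit between them. Genes of sonic hedgehog signalling, a mitogenic pathway of granule cell precursors, were all above the mean of the other arrays in the cerebellum (10 of 10, median 0.80), with the co-receptor gene Boc past the rule by 1.42. In the pontine nucleus their median was -0.81, or -0.36 against the lowest of the other arrays, with Gli3 at 8.04 against at least 9.86 and Boc at 8.46 against at least 9.74 called lower. Neural progenitor and radial glia genes lay above the mean of the others in the cerebellum for 13 of 14 members, with a median of 0.49, or 0.14 against the highest of the other arrays, and no member past the rule. The largest differences there were those of Id3, at 10.02 in the cerebellum against 8.81 to 9.38, and Slc1a3, at 12.58 against 11.38 to 12.33.

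**Figure D3:**
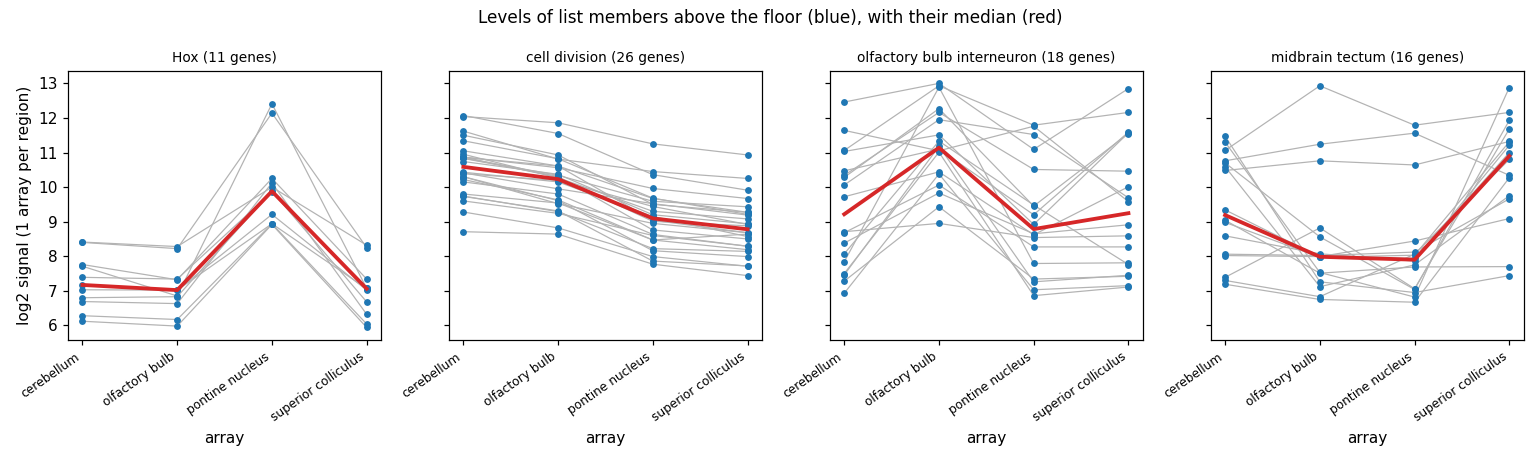
Log2 signal (vertical axis) of the members above the level floor of 4 gene lists on the 4 arrays (horizontal axis); each blue point is a gene on 1 array, grey lines join the points of a gene, and the red line is the median. The 11 Hox genes peak in the pontine nucleus, and the 26 cell division genes are lower in the pontine nucleus and the superior colliculus than in the cerebellum and the olfactory bulb.

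Synaptic genes went the other way in the cerebellum. Of 19, 18 lay below the mean of the other arrays there, with a median of -0.50, or -0.25 against the lowest of the other arrays, and none past the rule. Camk2a read 9.29 in the cerebellum against 11.46 in the olfactory bulb, 9.65 in the pontine nucleus and 10.50 in the superior colliculus. The synapsin gene Syn2 read 10.42 there against 11.31, 10.94 and 11.04. Of 25 cadherin and protocadherin genes, 21 lay above the mean of the others in the superior colliculus, with a median of 0.60, or 0.39 over all 29 measured genes, and Pcdh18, Cdh13 and Pcdh8 past the rule by 1.33, 1.32 and 1.04. In the pontine nucleus the cadherin median was -0.65, or -0.16 against the lowest of the other arrays, and Cdh12, Cdh4, Pcdh11x and Cdh10 were among 5 called lower, with Cdh12 at 8.21 against at least 10.32. The 40 axon guidance genes had medians between -0.12 and 0.10 on all 4 arrays, but single members differed widely. Besides Sema3a, Efnb2 was higher in the olfactory bulb by 1.76 and Sema3e by 1.75, while Epha7 was lower there at 9.83 against at least 11.57. Nrp1 and Robo3 were higher in the pontine nucleus by 1.28 and 1.23, and Slit1 in the superior colliculus by 1.11. Glycinergic neuron genes had a median of -0.81 over 6 members in the olfactory bulb and 0.47 in the cerebellum, where Pax2 passed. Glra1 was lower in the bulb, at 7.03 against at least 8.11. Measured against the lowest of the other arrays, the bulb median was only -0.08. That comparator was chosen for low lists after seeing the data.

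The random lists matched on mean level describe how far these medians stood from other genes on the same arrays. All 10000 random lists lay below the observed median for the granule lineage list in the cerebellum and in the pontine nucleus, the Purkinje list in the cerebellum, the Hox list in the pontine nucleus, the mitral, interneuron and telencephalon lists in the olfactory bulb, the tectum list in the superior colliculus, and the cell division and sonic hedgehog lists in the cerebellum. For the GABAergic progenitor list in the cerebellum 9956 random lists lay below, and for the mossy fibre list 9807 in the pontine nucleus and 9990 in the cerebellum. Such counts were at their limit for many lists and do not single out the regional ones. Of 152 medians, 1 per array and list without the background set, 20 lay above all random lists and 25 below all of them. Among the 20 were the ribosomal protein list, with medians of only 0.13 in the cerebellum and in the olfactory bulb, and the Purkinje list in the superior colliculus, with 0.53. These counts describe 4 arrays and are not a test between regions. Genes of a list are not independent of each other, and 11 of the 14 mossy fibre genes and 7 of the 21 measured granule lineage genes also belong to another list. The same holds for all 7 measured GABAergic neuron genes, 8 of 19 bulb interneuron genes, 5 of 11 mitral and tufted cell genes and 6 of 20 tectum genes. Results of lists that share genes are therefore not separate.

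Compared in pairs, the olfactory bulb and the pontine nucleus were the furthest apart. The closest pair depended on the size rule, being the cerebellum and the olfactory bulb at 1 log2 unit and the cerebellum and the superior colliculus at 2, where 89 genes differed against 113. Between the bulb and the pontine nucleus 847 genes differed by at least 1 log2 unit, 567 of them higher in the bulb, and Pearson's r across genes was 0.869. Nts, Eomes and Tbr1 had the largest differences towards the bulb, at 11.78, 12.21 and 12.22 against 5.62, 6.66 and 6.87. Mab21l2, Hoxa2 and Barhl1 had the largest towards the pontine nucleus, at 13.37, 12.41 and 12.50 against 7.73, 6.85 and 8.05. Between the cerebellum and the bulb 493 genes differed, 225 higher in the cerebellum and 268 in the bulb, with an r of 0.910. There Arhgef33, En2 and Calb1 were higher in the cerebellum by 4.96, 4.21 and 3.95, and Nts, Dlx1 and Tbr1 read 11.78, 12.89 and 12.22 in the bulb against 6.57, 7.84 and 7.98. Genes are not independent replicates, so these correlations carry no error.

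The pontine nucleus had the smaller number of higher genes in each pair it entered. Against the cerebellum 695 genes differed, with 490 higher in the cerebellum and 205 in the pontine nucleus and an r of 0.897. Neurod1, Arhgef33 and Islr2 were higher in the cerebellum by 5.45, 4.68 and 4.53. Hoxa2, Gabrg1 and Hoxb3 read 12.41, 12.52 and 12.14 in the pontine nucleus against 7.71, 8.68 and 8.40. Against the superior colliculus 637 genes differed, 188 higher in the pontine nucleus and 449 in the superior colliculus, with an r of 0.905. Hoxa2, Hoxb3 and Hoxa3 were higher in the pontine nucleus by 5.34, 3.89 and 3.80. Tfap2b, the tachykinin gene Tac1 and Otx2, a forebrain and midbrain homeobox gene, read 12.88, 10.16 and 11.93 in the superior colliculus against 6.82, 5.19 and 7.04.

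Between the cerebellum and the superior colliculus 623 genes differed, 336 higher in the cerebellum and 287 in the superior colliculus, with an r of 0.904. Arhgef33, En2 and Pgm5 were higher in the cerebellum by 4.75, 4.03 and 3.89, and Tfap2d, Gata3 and Tcf7l2 read 11.68, 10.80 and 12.88 in the superior colliculus against 7.39, 7.30 and 9.70. Between the olfactory bulb and the superior colliculus 619 genes differed, 321 higher in the bulb and 298 in the superior colliculus, with an r of 0.897. Tbr1, Eomes and Dlx1 were higher in the bulb by 5.47, 5.36 and 5.08. Tfap2b, Mab21l2 and Gata3 read 12.88, 12.51 and 10.80 in the superior colliculus against 7.53, 7.73 and 6.83. With a difference of 2 log2 units every pair count was smaller by more than 1.5 times, from 89 for the cerebellum and superior colliculus to 207 for the olfactory bulb and pontine nucleus.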

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

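The lowest of the other arrays as comparator was chosen after seeing the data. Quantile normalization and the mean of a gene's probe sets moved no count of genes by over 1.5 times. They moved no list median by more than 1 SD of its matched random lists. That SD is a spread over draws of genes on the same arrays. It is wider for small lists and does not measure variation between replicates. Quantile normalization shifted the median gene by at most 0.025 log2 units and kept 66 of the 66 higher genes in the cerebellum, 105 of 106 in the olfactory bulb, 76 of 87 in the pontine nucleus and 75 of 78 in the superior colliculus. Dropping the level floor or taking it from the background genes also left all 14 gene counts within 1.5 times. All 60 genes named for regions stayed past the rule under these 4 settings and against the mean of the other arrays. Most of that was fixed in advance. Dropping or lowering the floor cannot remove a gene, nor can the mean of the others as comparator, and only Plp2 had several probe sets. Quantile normalization was the setting that could have removed any of them. With the floor at the 75th percentile 54 stayed, and with the 2 log2 unit rule 51. The size rule and the comparator set the counts. In the order cerebellum, olfactory bulb, pontine nucleus and superior colliculus, the rule of 2 log2 units gave 12, 37, 21 and 15 higher and 0, 5, 13 and 1 lower genes, and the mean of the other arrays gave 264, 255, 180 and 241 higher and 100, 168, 395 and 179 lower. The floor at the 75th percentile, which leaves fewer genes to compare, gave 41, 65 and 49 higher genes in the cerebellum, olfactory bulb and superior colliculus. For pairs, the rule of 2 log2 units gave 113 genes for cerebellum and olfactory bulb, 115 for cerebellum and pontine nucleus, 89 for cerebellum and superior colliculus, 207 for olfactory bulb and pontine nucleus, 119 for olfactory bulb and superior colliculus and 132 for pontine nucleus and superior colliculus. The floor at the 75th percentile gave 309, 431, 369, 523 and 377 for the first 5 of these pairs. List medians were followed in 1 region each. For 9 regional lists this was their own region, a choice made after the values were seen. For the others it was the region whose median was largest in size, whether positive or negative. A median of at least 0.5 in size that changed sign is given as reversed. Against the highest of the other arrays, a comparator that can only lower a median, they were -0.17 for the granule lineage in the cerebellum (reversed), 0.82 for Purkinje cells, -0.47 for mossy fibre neurons, -1.28 for glycinergic neurons in the olfactory bulb, where the list was already low, 0.71 for the telencephalon, 0.84 for mitral cells, 0.85 for bulb interneurons, 1.39 for the tectum and -0.055 for neuropeptides in the olfactory bulb (reversed). For lists that lay low, the lowest of the other arrays is the strict comparator. It gave -0.08 for glycinergic neurons in the olfactory bulb, -0.75 for GABAergic neurons, -0.36 for sonic hedgehog signalling, -0.16 for cadherins and 0.425 for astrocytes in the pontine nucleus, -0.25 for synaptic genes in the cerebellum, and 0.08 for sensory ganglia in the olfactory bulb and 0.27 for glutamatergic neurons in the cerebellum (both reversed). With no floor the medians were 0.63 for cerebellar GABAergic progenitors, 1.66 for Hox, 1.27 for the telencephalon, 1.13 for the tectum and -0.0317 for dopamine neurons in the superior colliculus (reversed). With the floor from the background genes the same 5 were 0.63, 2.59, 1.27, 1.43 and -0.0317, the last again reversed. With the floor at the 75th percentile the medians were 2.23 for GABAergic progenitors, 0.025 for mossy fibre neurons, 3.71 for Hox, 3.02 for mitral cells and 2.98 for the tectum. The first is the value of Pax2 alone. The Hox median rests on Hoxa2, Hoxb3, Hoxa3 and Hoxb2, since Hoxc5, Hoxa5, Hoxc4, Hoxa4, Hoxd3, Hoxb4 and Hoxb5 dropped out of that list. A gene passes a floor through its brightest array, so a stricter floor can raise a median by selection and is no sign of robustness. Among other lists, no floor and the floor from the background genes gave 0.0267 and 0.1067 for neuropeptides in the olfactory bulb, -0.0567 and -0.16 for olfactory sensory neurons there, and -0.34 in both for glutamatergic neurons in the cerebellum. Signal over background limits what these arrays show for dim genes, since the 95th percentile of the background genes was 7.32 against a floor of 8.56.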

Other observations

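The tests of motor neuron genes and of Gbx2 were written down after the lists had been summarised but before the values of the genes they rest on were seen. The test of the unlisted probe sets and the choice of every gene named in this part outside the lists, and of the lists plotted member by member, came after the values were seen.

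Neuropeptide genes differed by region. Of 12 above the floor, 9 lay above the mean of the other arrays in the olfactory bulb, with a median of 0.82, or 0.0267 over all 22 measured genes and -0.055 against the highest of the other arrays, and Nts, Trh and Npy passed the size rule by 4.96, 2.63 and 2.18. The somatostatin gene Sst was lower in the bulb, at 10.42 against at least 12.20. Adcyap1, the gene of the peptide PACAP, was higher in the pontine nucleus, at 11.36 against at most 9.45, while Tac1 was lower there, at 5.19 against at least 7.64. Glutamatergic neuron genes had a median of -0.71 over 5 members in the cerebellum, or -0.34 with no level floor and 0.27 against the lowest of the other arrays, and the AMPA receptor gene Gria1 was lower in the pontine nucleus, at 9.24 against at least 10.94.

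Over 8 astrocyte genes the medians were 0.34 in the cerebellum, 0.38 in the olfactory bulb, -0.39 in the pontine nucleus and -0.35 in the superior colliculus. Against the lowest of the other arrays the pontine median was 0.425, and the water channel gene Aqp4 was higher in the pontine nucleus by 1.43. Medians of the oligodendrocyte lineage lay between -0.30 and 0.13 over 8 genes, those of microglia between -0.25 and 0.25 over 6, and those of endothelium and pericytes between -0.18 and 0.10 over 11, with no member past the rule. Of the 10 choroid plexus genes measured only Sostdc1 lay above the floor, lower in the olfactory bulb at 7.28 against at least 8.89, and Ttr, the most abundant choroid plexus transcript, read 6.49 to 7.71. Erythroid, skeletal muscle and cartilage and bone genes had 2, 1 and 1 members above the floor and none past the rule, with medians between -0.46 and 0.44, -0.28 and 0.18, and -0.46 and 0.39. Sensory ganglion genes had 3 members above the floor, each high in another region: Tlx3 in the cerebellum by 1.67, Scn9a in the pontine nucleus by 1.17 and Pou4f1 in the superior colliculus by 3.08. Housekeeping genes had medians between -0.11 and 0.11 over 11 genes, immediate early genes between -0.33 and 0.37 over 6, sex-linked genes between -0.20 and 0.17 over 4, and ribosomal protein genes between -0.16 and 0.13 over 54.

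The choline transporter gene Slc5a7 and the vesicular acetylcholine transporter gene Slc18a3 were higher in the pontine nucleus by 2.59 and 1.65. A candidate explanation is tissue of the surrounding hindbrain with cranial motor neurons. The motor neuron genes Isl1, Prph and Phox2a had a median gap of -0.27 above the highest of the other arrays, where at least 1 had been set as the mark of such tissue and 95% of the background genes have gaps within 0.38 of their median. All 3 genes read below the floor on every array, at 6.76, 7.93 and 7.09 in the pontine nucleus, and a gene that dim excludes nothing, so the limit set in advance was too lax and motor neurons stay open. The acetylcholine synthesis gene Chat read 7.49 there against 7.24 in the cerebellum. Other brainstem tissue also stays open, since the serotonergic genes Slc6a4 and Tph2 read 8.85 against at most 7.45 and 8.19 against at most 6.59. Expression by the pontine neurons themselves was not tested.

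Tcf7l2, Lef1 and Lhx9 were higher in the superior colliculus by 3.18, 2.78 and 2.32, and these genes are also strong in the thalamus and pretectum, which lie next to it. Thalamic tissue in the dissected piece was tested with Gbx2, a thalamic gene, which read 7.96 there against 8.44 in the cerebellum, a gap of -0.48 where at least 1 had been set as the mark. A single gene below the floor on every array cannot show that a tissue is absent, so the limit set in advance was too lax and thalamic tissue stays open. Pretectal tissue, and expression in the tectum itself, may also account for the pattern and were not tested.

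Of the probe sets without an entry in the annotation table, 259 lay at least 1 log2 unit above the other arrays in the pontine nucleus, against 7, 17 and 8 in the cerebellum, olfactory bulb and superior colliculus. No level floor was applied here. The 259 were dim, with a median level of 7.11 in the pontine nucleus against 5.82 for the highest of the other arrays. The 95th percentile of the background genes was 7.32. A scaling offset of the pontine nucleus array at low signal would shift named probe sets of the same level too. Their median difference was -0.05 (95% interval -0.053 to -0.047 over 200 resamples), against 0.10 (0.093 to 0.107) for the unlisted ones, which argues against such an offset, although resampled probe sets are not independent. Of the 259, 224 belong to the 6617 probe sets numbered before the first listed one, of which 74.4% read higher in the pontine nucleus, with a median difference of 0.25. The other 5529 unlisted probe sets showed no shift of the median, at 0.00. Still, 35 of them passed the rule in the pontine nucleus, against 5 in the cerebellum, 11 in the olfactory bulb and 4 in the superior colliculus. The pattern thus lay mostly in that block, but not only there. What they target is not given in the sources used here, so a difference in the preparation of that RNA and a difference between the tissues both stay open.

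Ddx31, higher in the pontine nucleus at 11.31 against 8.25 to 8.51, lies next to Barhl1 in the RefSeq gene table of GRCm38.p6, and Barhl1 also read highest there, at 12.50 against 8.05 to 11.25. Ppp1r17, listed as a Purkinje cell gene, read 8.38 in the olfactory bulb and 5.93 in the cerebellum, both below the floor. Dcn, a fibroblast gene, read 10.59 in the olfactory bulb, where the collagen gene Col1a1 read 9.07 against 8.56 to 8.70 elsewhere.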
